A study of Mus musculus with 4 samples.

How the data were processed

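MAIT cells from the thymus, spleen, lung and liver of untreated C57BL/6 mice were profiled by droplet single-cell RNA sequencing, with 1 library per tissue. MAIT cells are T cells that recognise microbial riboflavin metabolites presented by MR1. Per the labels' protocols, the spleen and the thymus were disrupted mechanically, the liver was disrupted mechanically and passed over Percoll, and only the lung was digested with enzymes. Cells carrying CD11b, CD11c, F4/80, CD19 or TER-119 were removed with magnetic beads, and the MAIT cells were then sorted by flow cytometry. The number of animals behind each library, their sex and the sort gate were not stated. Libraries used 10x v2 chemistry, and the submitters' processing notes name Cell Ranger and mm10, with versions not given in the sources used here.

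The authors deposited a table of raw UMI counts for 13503 genes in 6080 cells, whose column totals equalled the total counts per cell in their cell annotation. The deposited normalized table held natural log values, checked to be ln(1 + 10000 × count / cell total) with every difference under 1e-06, and it was not used further. Per the file headers, the cell annotation gave the tissue, the library and cluster numbers at resolutions 0.4, 0.6 and 0.8, with 9, 11 and 13 clusters. Its mitochondrial column, named as a percentage, held the fraction of UMIs from mitochondrially encoded genes, per the file headers and a recount from the deposited values. Cells had evidently been filtered before deposit, since no cell exceeded 2486 detected genes or 5.00% mitochondrial UMIs, but no source states the thresholds. The table held 0 T cell receptor gene names, so the MAIT receptor could not be checked and the lists of MAIT, iNKT and gamma-delta receptor genes had 0 measured members.

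The thymus library held 598 cells and 2056243 UMIs, the spleen library 3145 cells and 8306210 UMIs, the lung library 1313 cells and 2832510 UMIs, and the liver library 1024 cells and 3100079 UMIs. Median depth per cell was 2892, 2393, 2079 and 2820 UMIs in the same order. A count of 0 cells therefore allows a share of up to 0.502% of thymus, 0.0954% of spleen, 0.228% of lung and 0.293% of liver cells, taking 3 counts as the limit. Intervals between tissues are exact 95% intervals for CPM (Poisson, counts scaled to the class total) and for shares (Clopper-Pearson), and for list medians are simulated from 200 Poisson draws of the counts. All cover counting error only. Library names carried 2 date-like codes, one shared by the spleen and liver and the other by the lung and thymus.

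The authors' clusters at resolution 0.4 were named from marker genes fixed before the data were examined, as were the gene lists, the tests, the rule for named genes and the alternatives unless stated otherwise. Clusters 0, 3 and 5 were called MAIT17-like, from Rorc, Il23r, Blk and related markers, and cluster 1 MAIT1-like, from Tbx21, Cxcr3, Xcl1 and killer lectin receptors. Clusters 2 and 4 were called naive T-like, cluster 6 precursor-like and cluster 7 cycling-like. Cluster 8, led by Gzma, Ccl5 and Gzmk, stayed unnamed. Clusters 3 and 5 had no MAIT17-like marker among their 10 leading genes and none of another class either, and were named from marker levels, with Rorc at 63.2 and 125 CPM against 123 in cluster 0 and 11.3 in cluster 1. The resolution was chosen after cluster sizes had been seen. Scrublet (scanpy 1.11.5) called 46 of 6080 cells doublets (0.757%), which were kept in the main results.

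To compare the classes, raw UMI counts were summed per tissue and class, giving 8 sums of at least 20 cells, the smallest of 46 cells. They were tested with edgeR 4.0.16 (TMM scaling, filterByExpr, the quasi-likelihood test, two-sided) with the tissue library as a block, since both classes of a tissue come from 1 library. P-values were adjusted by the Benjamini-Hochberg method at 0.05, and robust dispersions were a choice made after the data were seen. The SE of a log2 difference was back-calculated, as its absolute value divided by the square root of the quasi-likelihood F. The 4 tissues served as the samples, so the spread is between tissues and not between animals. Since the clusters were built from these same counts, the class p-values are not independent evidence of separate cell types. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, beside camera with an estimated correlation and fry. R was 4.3.3. On simulated sums with the real means and depths, over 8507 genes, the test recovered 87 of 100 genes changed 2-fold and 100 of 100 changed 4-fold, and 8 of its 195 calls (4.10%) were unchanged genes. The simulation used 1 dispersion (0.0129) for all genes and changed only genes averaging at least 20 CPM, alike in all tissues. Its rates do not cover genes whose class difference varies more between tissues, nor classes clustered from the same counts.

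Named genes between the classes were the 12 with the largest change each way among those past the threshold, averaging at least 50 CPM and with the same direction in all 4 tissues. Marker lists, other-cell-type lists, receptor and immunoglobulin segments and unnamed transcripts were excluded, and from each list the members with the smallest p were added. Across tissues no test was run. Within a class, a gene's value in 1 tissue was compared with each other tissue as log2 of CPM plus a pseudocount of 20, and the 8 genes standing furthest above and below all other tissues were eligible where the higher sum held at least 30 UMIs. For a list, the median over members of the tissue's log2 value minus the mean of the other 3 was ranked among 10000 random lists of the same size matched on expression. Lists with a median of at least 0.4 either way and a percentile of at most 1 or at least 99 were the first to be described, a rule set after the data were seen. Shares of cells with a UMI were computed after thinning each cell to 1000 UMIs, which left out 69 spleen, 74 lung, 11 liver and 0 thymus cells. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9. Gene positions are from GENCODE vM21 on GRCm38, the assembly of mm10, where 222 of 225 symbols matched.

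Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no low-count filter, no block, each tissue left out in turn, rebuilt clusters (Leiden at resolution 0.5, 2000 variable genes, 20 principal components, 15 neighbours, 10 clusters), and rebuilt clusters without 479 list genes. The B cell, myeloid, gamma-delta and interferon marker sets were kept out of the naming of rebuilt clusters, a choice made after the data were seen. Further ones were classes from one portion of each cell's UMIs tested on the rest, classes from the markers alone, thinned cells, no called doublets, other pseudocounts and list filters, and all cells of a tissue in place of a class. Added after the data were seen were cluster 0 alone as MAIT17-like, cluster 8 as MAIT1-like, dispersions without the robust option, and the interferon-high cluster left out. Naive T-like, precursor-like, cycling-like and unnamed cells stayed out of the main class test. Classes from the markers alone took in such cells, as each cell went to the class with more marker UMIs.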

Results

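Single-cell transcriptomes of sorted MAIT cells were collected from 4 organs of untreated mice, with 1 library each for the thymus, spleen, lung and liver. The thymus gave 598 cells and 2056243 UMIs, with a median of 2892 UMIs and 1257 genes per cell. The spleen gave 3145 cells and 8306210 UMIs, with medians of 2393 UMIs and 1016 genes. The lung gave 1313 cells and 2832510 UMIs, with medians of 2079 UMIs and 951 genes, and the liver 1024 cells and 3100079 UMIs, with medians of 2820 UMIs and 1209 genes. The median share of mitochondrial UMIs per cell was 3.12%, 3.18%, 3.67% and 2.52% in thymus, spleen, lung and liver. There was no replicate library for any tissue, so values that compare tissues carry counting error only, as 95% intervals in parentheses, and differences in mice, sorting or tissue preparation stay within them.

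The 6080 cells fell into 9 clusters, which marker genes placed in 5 named classes and 1 unnamed group. MAIT17-like cells expressed Rorc, the transcription factor of the IL-17 programme, at 63.2 to 125 CPM in their 3 clusters, against 11.3 CPM in the MAIT1-like cluster. MAIT1-like cells expressed Tbx21, the transcription factor of the interferon-gamma programme, at 61.5 ± 18.0 CPM against 2.36 ± 0.492 CPM in MAIT17-like cells (mean and SD, n = 4 tissues). Naive T-like cells expressed the lymph node homing genes Ccr7, at 227 and 273 CPM in their 2 clusters, and Sell, at 194 and 322 CPM. One naive T-like cluster held Cd4 at 83.9 CPM and the other Cd8b1 at 1111 CPM. Precursor-like cells were led by Itm2a at 2555 CPM, Ccr9 at 573 CPM and Cd24a at 177 CPM, genes of maturing thymocytes. Cycling-like cells expressed the proliferation gene Mki67 at 408 CPM. The unnamed group carried the chemokine gene Ccl5 at 47161 CPM, the granzyme gene Gzmk at 456 CPM, Klrg1 at 349 CPM and Cx3cr1 at 215 CPM, with Cd8b1 at 1517 CPM.

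How the classes were distributed over the organs was the first question. MAIT17-like cells made up 78.98% of lung cells (76.7 to 81.2), 46.0% of spleen cells (44.2 to 47.7), 37.7% of liver cells (34.7 to 40.7) and 31.3% of thymus cells (27.6 to 35.2). MAIT1-like cells made up 52.8% of liver cells (49.7 to 55.9), 18.1% of thymus cells (15.1 to 21.4), 14.1% of spleen cells (12.9 to 15.4) and 3.50% of lung cells (2.58 to 4.65). Naive T-like cells were 37.4% of the spleen library (35.7 to 39.1), 13.9% of the thymus (11.2 to 16.9), 13.6% of the lung (11.8 to 15.5) and 8.69% of the liver (7.04 to 10.6). Precursor-like cells were 36.1% of the thymus (32.3 to 40.1) and 0.0954% of the spleen. There were 0 of 1313 precursor-like cells in the lung, which allows a share of up to 0.228%, and 0 of 1024 in the liver, which allows up to 0.293%. Cycling-like cells were 0.669% of thymus, 1.78% of spleen, 0.838% of lung and 0.488% of liver cells. The unnamed group was 3.12% of the lung, 0.636% of the spleen and 0.293% of the liver library, with 0 of 598 thymus cells, which allows a share of up to 0.502%. These shares describe cells that passed bead depletion and sorting, and the lung cells also enzymatic digestion and the liver cells Percoll. Classes drawn from the markers alone put the MAIT17-like share of thymus cells at 49.0% and the MAIT1-like share at 36.6%, 51.3%, 23.5% and 63.0% of thymus, spleen, lung and liver cells. These classes also took in naive T-like, precursor-like and other cells, so they are not shares of the same classes.

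**Figure D1:**
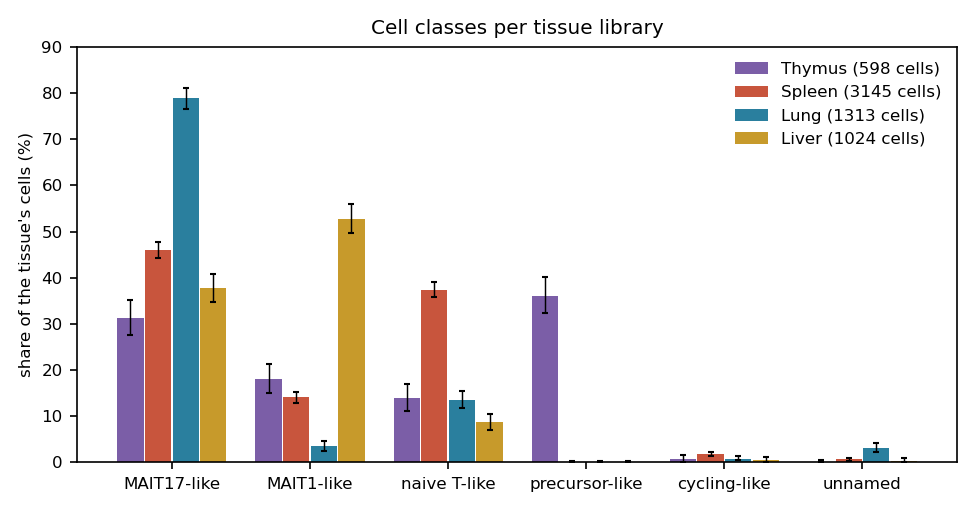
Share of each class in the thymus, spleen, lung and liver libraries, with exact Clopper-Pearson 95% intervals for counting error.

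Within the MAIT17-like class the lung differed in composition from the other organs. Cluster 3, led by the transcription factor genes Crem and Fosl2 together with Ramp3 and Vps37b, held 780 cells, all from the lung, which was 75.2% of lung MAIT17-like cells. Cluster 0, led by Fam83a and the kinase gene Blk, held 77.0%, 75.3% and 78.5% of MAIT17-like cells in thymus, spleen and liver and 22.0% in lung. Cluster 5, led by Ccr10 and the mitotic cyclin gene Ccnb2, held 23.0%, 24.7% and 21.5% in thymus, spleen and liver and 2.80% in lung. Naive T-like cells of the lung were 85.4% from the Cd8b1-expressing cluster, against 34.9%, 43.0% and 46.1% in thymus, spleen and liver. In the authors' finest clustering 118 of these 152 lung cells, with 2 of the other naive T-like cluster, formed a cluster led by Ccr7 and Gramd3 with 1 cell from another tissue, and 32 stayed in the Cd8b1-led one. That clustering also put 117 of the 228 lung cells of cluster 0 in a cluster led by heat shock genes. The values given below for a lung class therefore come largely from other clusters than those of the remaining tissues.

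Which genes separated MAIT17-like from MAIT1-like cells in all 4 organs was the second question. MAIT17-like cells expressed more Fam83a, which encodes a signalling protein, with a log2 difference of 4.04 ± 0.232 (SE) and means of 171 ± 52.7 against 10.3 ± 4.24 CPM (SD, n = 4 tissues). They expressed more Il17re, a subunit of the IL-17C receptor, with a log2 difference of 3.67 ± 0.268 and 115 ± 23.5 against 5.24 ± 6.39 CPM. MAIT1-like cells expressed more Slamf7, a SLAM-family surface receptor, with a log2 difference of -4.95 ± 0.247 and 114 ± 42.7 against 3.38 ± 0.788 CPM. They also expressed more Gimap4, a GTPase of lymphocytes, with a log2 difference of -3.80 ± 0.135 and 859 ± 304 against 63.8 ± 24.2 CPM. The rule that chose the 24 genes named here required the same direction in all 4 tissues, so that agreement is not further evidence for them.

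Of 8373 genes tested by edgeR, 905 were higher and 790 lower in MAIT17-like cells after Benjamini-Hochberg adjustment, and 1336 of these 1695 had the same direction in all 4 tissues. Without the liver 386 genes were higher and 425 lower, and without the spleen 501 and 529, while the DESeq2 Wald test gave 422 and 469. When 1 random part of each cell's UMIs defined the classes and the other part was tested, 467 genes were higher and 519 lower, and without the tissue block 363 and 356 were. The clusters had been built from these counts, so the p-values are not independent evidence, and 7 of the 24 genes named here (Fam83a, Il17re, Ramp3, Hk2, Avpi1, Acsbg1 and Gimap7) were among the leading genes of the clusters themselves. For the marker lists that named the classes, 21 of 23 tested members of the type 17 list were higher and 21 of 23 of the type 1 list lower in MAIT17-like cells, with medians of 3.12 and -4.19. Adjusted over the list alone, 21 and 22 passed, and the adjusted p = 0.0314 and 0.0145 with an estimated correlation. This is a check of the names and no more.

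Among genes higher in MAIT17-like cells, Lmna, which encodes nuclear lamins A and C, had a log2 difference of 3.62 ± 0.249 and means of 175 ± 187 against 22.8 ± 35.0 CPM. Ramp3, a partner of calcitonin-family receptors, had 3.46 ± 0.218 with 342 ± 464 against 22.5 ± 27.6 CPM, and lung cells held it at 1037 CPM. Hk2, the hexokinase that phosphorylates glucose, had 2.97 ± 0.229 with 209 ± 264 against 21.5 ± 19.3 CPM. Avpi1 had 2.81 ± 0.248 with 127 ± 131 against 15.05 ± 15.4 CPM. Nebl, an actin-binding protein, had 2.41 ± 0.246 with 87.2 ± 43.9 against 28.3 ± 32.2 CPM. Their edgeR adjusted p-values were 2.50e-21, 2.28e-21, 3.93e-18, 6.07e-16 and 2.31e-11, but all 5 lost the call without the tissue block, at 0.115, 0.117, 0.147, 0.0895 and 0.114.

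Sepp1, the secreted selenium carrier selenoprotein P, was higher in MAIT17-like cells by 2.83 ± 0.147, at 646 ± 85.6 against 93.1 ± 30.6 CPM, with an edgeR adjusted p of 6.98e-27. Acsbg1, which activates long-chain fatty acids, was higher by 2.71 ± 0.241, at 166 ± 72.9 against 26.8 ± 11.96 CPM. Furin, a protease that processes precursor proteins, was higher by 2.61 ± 0.401, at 340 ± 92.4 against 44.6 ± 30.5 CPM, but lost the call where the UMIs were divided between naming and testing, at 0.0931. Lgals3, which encodes galectin-3, differed by 3.57 ± 0.653, at 1239.9 ± 127 against 144 ± 95.04 CPM, and S100a4, a calcium-binding protein, by 3.02 ± 0.447, at 1286 ± 178 against 178 ± 89.1 CPM. These 2 genes passed narrowly, with edgeR adjusted p-values of 0.0447 and 0.0255. Lgals3 lost the call without the lung, at 0.109, or the spleen, at 0.205, and S100a4 at 0.0954 and 0.124.

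Among genes lower in MAIT17-like cells, Bcl2, which blocks apoptosis, had a log2 difference of -3.42 ± 0.172, at 32.2 ± 14.4 CPM in MAIT17-like and 312 ± 125 CPM in MAIT1-like cells. Gimap7 differed by -4.37 ± 0.248, at 9.83 ± 8.04 against 214 ± 147 CPM, and Gimap3 by -3.15 ± 0.167, at 61.5 ± 25.6 against 490 ± 140 CPM. Serpinb9, an inhibitor of granzyme B, differed by -2.80 ± 0.237, at 17.6 ± 20.95 against 123 ± 160 CPM, and Lyst, needed for secretory lysosomes, by -2.75 ± 0.216, at 14.2 ± 7.97 against 92.2 ± 50.2 CPM. Pglyrp1, which binds bacterial peptidoglycan, differed by -3.50 ± 0.206, at 10.8 ± 5.59 against 137 ± 37.5 CPM. Inpp4b, a lipid phosphatase, differed by -3.54 ± 0.223, at 9.43 ± 1.76 against 112 ± 57.1 CPM, and the class I gene H2-Q6 by -3.18 ± 0.182, at 19.3 ± 9.27 against 157 ± 29.9 CPM. Gramd3 differed by -3.84 ± 0.213, at 12.03 ± 13.2 against 162 ± 94.7 CPM, and Plac8 by -4.76 ± 0.558, at 6.73 ± 3.94 against 204 ± 116 CPM.

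The edgeR adjusted p was 3.46e-38 for Gimap4, 2.87e-29 for Slamf7, 1.04e-25 for Fam83a and 0.00914 for Plac8. Plac8 lost the call with rebuilt clusters, at 0.188, and with classes from the markers alone, at 0.0620, where Bcl2 lost it too, at 0.0892. Marker-only classes also took in naive T-like and other cells. Serpinb9 lost the call without the tissue block, at 0.425. On GRCm38, Fam83a lies at chromosome 15 from 57985419 to 58011009, Il17re at chromosome 6 from 113458484 to 113470758, Slamf7 at chromosome 1 from 171632403 to 171653035 and Gimap4 at chromosome 6 from 48684549 to 48692060.

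**Figure D2:**
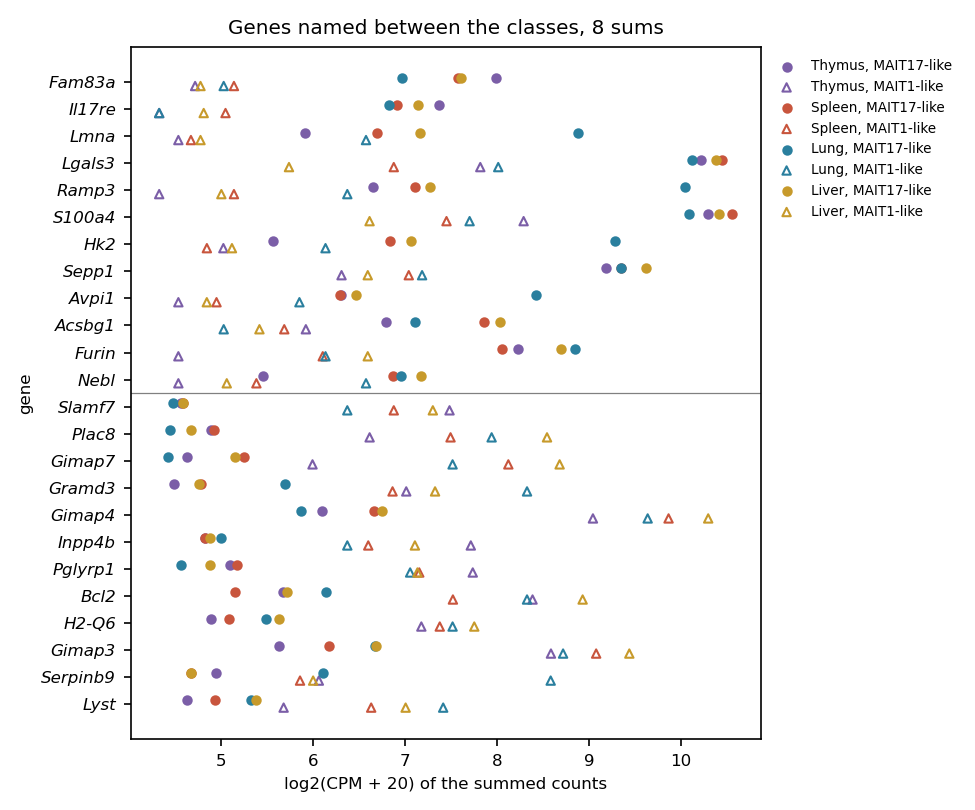
Expression of the 24 named genes in each class and tissue, as log2 of CPM plus 20, with 12 genes higher in MAIT17-like and 12 higher in MAIT1-like cells.

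Transcription factor and cytokine genes of the 2 programmes differed alongside. Il17a and Ifng were among the markers that named the classes, so their differences are a check of the names. Zbtb16, which encodes the innate-like T cell factor PLZF, was higher in MAIT17-like cells by 1.22 ± 0.169, at 123 ± 26.3 against 50.5 ± 9.49 CPM, with an edgeR adjusted p of 1.13e-08 and 4 of 4 tissues alike. Il17a was higher by 4.87 ± 0.455, and Ifng by -4.97 ± 0.284, lower in MAIT17-like cells, at 76.6 ± 53.9 CPM in MAIT1-like and 2.52 ± 1.03 CPM in MAIT17-like cells. Il7r, the IL-7 receptor, differed by 0.82 ± 0.311 with an edgeR adjusted p of 0.211 although 4 of 4 tissues were higher, and Cd44 by 0.33 ± 0.156 with 0.133. Cxcr6 stood at 856 ± 85.9 and 909 ± 380 CPM, with a log2 difference of -0.19 ± 0.421.

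The cytotoxicity genes were lower in MAIT17-like cells, with 7 of 8 tested members lower and 1 not passed (10 measured), 7 adjusted over the list alone. The perforin gene Prf1 differed by -3.71, at 1.87 ± 0.490 against 26.1 ± 10.0 CPM, the death ligand gene Fasl by -3.77 and the cathepsin gene Ctsw by -2.55, while Gzmb, at -2.33, did not pass (edgeR adjusted p = 0.209, 3 of 4 tissues lower). The list median was -2.74 and the camera adjusted p 2.16e-11, lost at adjusted p = 0.113 with an estimated correlation. Markers of NK cells and innate lymphoid cells were lower alongside, in 6 of 6 tested members. Among them Klrb1c stood at 32.4 ± 16.7 against 297 ± 63.0 CPM, Klra9 at 2.60 ± 3.31 against 400 ± 517 CPM and Tyrobp at 1.09 ± 1.21 against 73.4 ± 85.0 CPM. Klrb1c was itself among the markers that named the MAIT1-like class. Tyrobp stood at 201 CPM in lung MAIT1-like cells against 21.8 to 36.8 CPM in those of the other tissues. Fcer1g, an adaptor of the myeloid list that NK cells also express, stood at 4.29 ± 4.26 against 201 ± 163 CPM.

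The interferon response genes were lower in MAIT17-like cells, with 13 of 14 members lower and 1 not passed, 13 adjusted over the list alone. Ifi27l2a differed by -2.34, at 132 ± 62.5 against 634 ± 272 CPM, Stat1, which carries interferon signals, by -1.40, at 97.8 ± 41.4 against 231 ± 61.4 CPM, and Irf7 by -1.48. Oasl2, at 0.14, did not pass. The list median was -2.13 and the camera adjusted p 2.69e-12, lost at adjusted p = 0.408 with an estimated correlation. Ifit3b had 3 UMIs in all MAIT17-like cells and 77 in MAIT1-like cells, with ratios of 36.9 (5.61 to 1560) in thymus and 44.9 (10.8 to 397) in spleen, counting error only. In liver it was at least 12.7-fold higher in MAIT1-like cells, and in lung it had 0 UMIs in both classes. A cluster of 84 interferon-high cells in the authors' finest clustering held 81 MAIT1-like and 3 MAIT17-like cells, and without it 11 members were still called.

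The ribosomal protein genes were slightly lower in MAIT17-like cells, with 41 of 77 tested members lower, 4 higher and 32 not passed (78 measured), and 45 lower and 6 higher adjusted over the list alone. Rps27 differed by -0.62 and Rps23 by -0.47, while Rps27l, a p53 target, was higher by 0.72. The list median was -0.21 and the camera adjusted p 8.92e-07, lost at adjusted p = 0.578 with an estimated correlation. Genes of thymic precursors were lower in 5 of 10 tested members (15 measured), higher in 0 and not passed in 5, with 5 lower adjusted over the list alone. Lef1, a factor of naive and immature T cells, differed by -1.68, at 46.0 ± 6.05 against 155 ± 55.6 CPM, and Itm2a by -3.33, while Tox, at -0.03, and Cd8a, at -0.25, did not pass. The list median was -0.47 and the camera adjusted p 0.00507, lost at adjusted p = 0.346 with an estimated correlation and at 0.101 without the tissue block.

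Proliferation genes were higher in MAIT17-like cells, with 10 of 16 tested members higher, 0 lower and 6 not passed (17 measured), 11 adjusted over the list alone. The mitotic genes Ccnb2, by 3.67 at 32.8 ± 20.6 against 1.96 ± 3.09 CPM, and Birc5, by 3.26, led the list with Mki67, by 1.61. The replication genes Mcm6, at -0.29, Pcna, at -0.24, and Mcm3, at 0.02, did not pass. The list median was 1.60 and the camera adjusted p 0.00108, lost at adjusted p = 0.476 with an estimated correlation. It was also lost at 0.230 without the tissue block, at 0.0682 with clusters rebuilt without list genes and at 0.245 with cluster 8 as MAIT1-like. The direction turned where the UMIs were divided between naming and testing, with a list median of -0.61 and 0.0553, and with cluster 0 alone as MAIT17-like, with -0.26 and 0.161. The Ccnb2-led cluster 5 belonged to the MAIT17-like class.

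Genes of lipid uptake and storage were higher in MAIT17-like cells, with 6 of 11 tested members higher, 0 lower and 5 not passed (19 measured). Adjusted over the list alone, 8 were higher and 1 lower. The lipid droplet gene Plin3 differed by 2.22, at 128 ± 40.8 against 23.0 ± 15.9 CPM, the fatty acid carrier Fabp5 by 1.48, the lipoprotein receptor Scarb1 by 1.96 and Dgat1, which makes triglycerides, by 0.93. Fabp5 lost the call without the spleen, at 0.0726. The list median was 0.78 and the camera adjusted p 0.00306, lost at adjusted p = 0.346 with an estimated correlation, at 0.0850 without the tissue block and at 0.0710 with cluster 0 alone. Fatty acid oxidation had 4 of 18 members higher, 0 lower and 14 not passed, and 5 higher adjusted over the list alone, among them Acadm by 1.07 and Echs1 by 0.63. Its median was 0.19 and its camera adjusted p 0.133. Cholesterol and fatty acid synthesis had 1 of 17 tested members higher (21 measured), Dhcr24 by 3.19 at 24.3 ± 7.53 against 2.05 ± 1.83 CPM, 0 lower and 16 not passed, and 1 higher adjusted over the list alone. Its median was 0.07 and its camera adjusted p 0.868.

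Respiratory chain genes encoded in the nucleus were slightly higher in MAIT17-like cells, with 12 of 74 tested members higher, 1 lower and 61 not passed (75 measured), 10 higher adjusted over the list alone. The complex I genes Ndufs5, by 0.83 at 299 ± 44.1 against 156 ± 27.1 CPM, and Ndufa1, by 0.74, led it, and Cox8a was lower, by -0.27. The median was 0.19 and the camera adjusted p 0.000295, lost at adjusted p = 0.476 with an estimated correlation, at 0.106 where the UMIs were divided between naming and testing and at 0.0666 with cluster 8 as MAIT1-like. The mitochondrially encoded chain had 7 of 13 members higher, 0 lower and 6 not passed, 8 higher adjusted over the list alone, with mt-Co3 higher by 0.29 and mt-Atp6 by 0.24. Its median was 0.22 and its camera adjusted p 0.00801, lost at adjusted p = 0.609 with an estimated correlation, at 0.160 without the tissue block, at 0.266 without the liver, at 0.102 without the lung and at 0.0651 with cluster 8 as MAIT1-like. Without the liver mt-Co3 stood at 0.192 and mt-Atp6 at 0.292. The TCA cycle had 3 of 17 tested members higher (19 measured), 0 lower and 14 not passed, 3 higher adjusted over the list alone, with Idh3a by 0.90 and Sucla2 by 0.78. Its median was 0.17 and its camera adjusted p 0.110.

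Glycolysis was mixed, with 6 of 17 tested members higher, 2 lower and 9 not passed (18 measured), and 7 higher and 3 lower adjusted over the list alone. Besides Hk2, Ldha, which makes lactate, was higher by 0.61 at 649 ± 111 against 397 ± 51.3 CPM and Pfkp by 0.69, while the glucose transporters Slc2a3, by -1.43, and Slc2a1, by -1.17, were lower. The median was 0.22 and the camera adjusted p 0.225. Antioxidant genes had 6 of 15 tested members higher, 2 lower and 7 not passed (17 measured), and 8 higher and 2 lower adjusted over the list alone. Gpx1, a glutathione peroxidase, was higher by 1.88 at 404 ± 17.9 against 95.7 ± 27.0 CPM and Gclc, for glutathione synthesis, by 2.29, while Gpx4, by -0.63, and Nfe2l2, by -0.73, were lower. The median was 0.33 and the camera adjusted p 0.0557, or adjusted p = 0.414 with an estimated correlation. The camera value became 0.0293 without the liver, 0.0376 without the lung and 0.0410 without the tissue block, each lost with an estimated correlation, at adjusted p = 0.426, 0.415 and 0.230.

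Tissue repair genes had 2 of 9 tested members higher in MAIT17-like cells, 0 lower and 7 not passed (13 measured), 2 adjusted over the list alone. These were Furin, given above, and Il22, a cytokine acting on epithelium, which had 174 UMIs in MAIT17-like and 0 in MAIT1-like cells. Il22 was at least 12.7-fold higher in liver, 1.62-fold in spleen and 1.37-fold in lung, and in thymus its 2 UMIs were too few for a bound. Areg had 77 of its 81 MAIT17-like UMIs in the lung, with a ratio there of 2.72 (0.475 to 109, counting error only) to the 1 UMI of MAIT1-like cells, and did not pass (edgeR adjusted p = 0.376, 2 of 4 tissues higher). The median was 0.46 and the camera adjusted p 0.0169. The call was lost at adjusted p = 0.416 with an estimated correlation, at 0.334 without the lung, at 0.134 without the tissue block and at 0.0687 without interferon-high cells.

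Chemokine receptor genes were divided between the classes, with 3 of 12 tested members higher in MAIT17-like cells, 3 lower and 6 not passed (15 measured), and 4 higher and 3 lower adjusted over the list alone. Ccr6 was higher by 4.25, at 125 ± 20.97 against 7.32 ± 7.03 CPM, Ccr4 by 2.04 and Ccr2 by 0.98, while Cxcr3, by -4.18 at 14.5 ± 7.05 against 256 ± 58.5 CPM, Ccr5, by -3.71, and Ccr9, by -2.75, were lower. Ccr6 and Cxcr3 were among the markers that named the classes, so their differences are a check of the names. The list median was 0.09, fry pointed down and the camera adjusted p was 0.868. The type 2 list had 3 of 7 tested members higher, 3 lower and 1 not passed, and 4 higher and 3 lower adjusted over the list alone. Its cytokine gene Il4 was lower, by -4.82, while Il17rb, the IL-25 receptor, was higher, by 2.39, and the costimulator Icos by 1.70. Its median was 0.32 but its mean -0.63, fry pointed down and the camera adjusted p was 0.868.

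Tissue residency genes had 1 of 14 tested members higher in MAIT17-like cells, 3 lower and 10 not passed (16 measured), as when adjusted over the list alone. Rgs1, which dampens chemokine signals, was lower by -1.45 and Bhlhe40 by -1.53, Odc1 was higher by 0.52, and Itga1 had 2 UMIs in MAIT17-like and 43 in MAIT1-like cells. Itga1 was at least 12.3-fold higher in MAIT1-like cells of the thymus and 4.73-fold in spleen, with a ratio of 22.4 (3.69 to 920, counting error only) in liver, and in lung its 1 UMI was in MAIT17-like cells. The median was -0.19 and the camera adjusted p 0.373, which became 0.0176 without the lung, lost there at adjusted p = 0.415 with an estimated correlation. Recirculation genes had 3 of 10 tested members higher, 2 lower and 5 not passed (11 measured), as when adjusted over the list alone. The gut-homing integrin gene Itgb7 was higher by 1.03 and S1pr4 by 0.70, while Sidt1, by -1.75, and Klf3, by -1.32, were lower, and the median was 0.30, the mean -0.21 and the camera adjusted p 0.868.

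Immediate early and stress genes had 4 of 21 tested members higher, 1 lower and 16 not passed (23 measured), as when adjusted over the list alone. Fosb was higher by 1.24 and Zfp36 by 0.74, and both lost the call without the liver, at 0.0887 and 0.262. The median was -0.09 but the mean 0.08, fry pointed up and the camera adjusted p was 0.891. NF-kB target genes had 1 of 15 members higher, 4 lower and 10 not passed, as when adjusted over the list alone, with Traf1 lower by -1.19, Icam1 by -0.97 and Nfkb1 higher by 0.65. The median was -0.14 and the camera adjusted p 0.868. T cell receptor signalling genes had 2 of 10 tested members higher, 2 lower and 6 not passed (14 measured), as when adjusted over the list alone. The inhibitory receptor gene Pdcd1 was higher by 1.46, Tnfrsf9 was lower by -2.38, and Cd5 was lower by -0.68, a call lost at 0.230 without the liver. The median was -0.07 and the camera adjusted p 0.496.

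The fry test asks whether a list moved on balance in 1 direction, and does not compare it with other genes. Of the 9 lists called by camera, fry gave 0.0125 for cytotoxicity and 0.0218 for tissue repair, but 0.0531 for lipid uptake and for precursor genes, 0.0608 for nuclear-encoded and 0.0884 for mitochondrially encoded respiration, 0.0789 for ribosomal, 0.0884 for interferon response and 0.116 for proliferation genes. It gave 0.0125 for the antioxidant list, which camera did not call.

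Among markers of other cells besides NK cells, the B cell gene Cd79b stood at 52.1 ± 24.6 CPM in MAIT17-like and 7.29 ± 6.48 CPM in MAIT1-like cells, a log2 difference of 2.76, and Cd74 at 45.9 ± 18.3 and 23.8 ± 22.1 CPM. The double-positive thymocyte gene Ptcra stood at 6.47 ± 1.34 and 6.57 ± 5.64 CPM. The neutrophil gene S100a8 stood at 19.5 ± 8.29 and 21.4 ± 3.87 CPM. No hepatocyte, lung epithelial or erythroid marker was expressed enough to be tested. Xist, from the inactive X chromosome, stood at 1019 ± 136 and 906 ± 176 CPM, with a log2 difference of 0.11 (edgeR adjusted p = 0.490, 4 of 4 tissues higher).

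**Figure D3:**
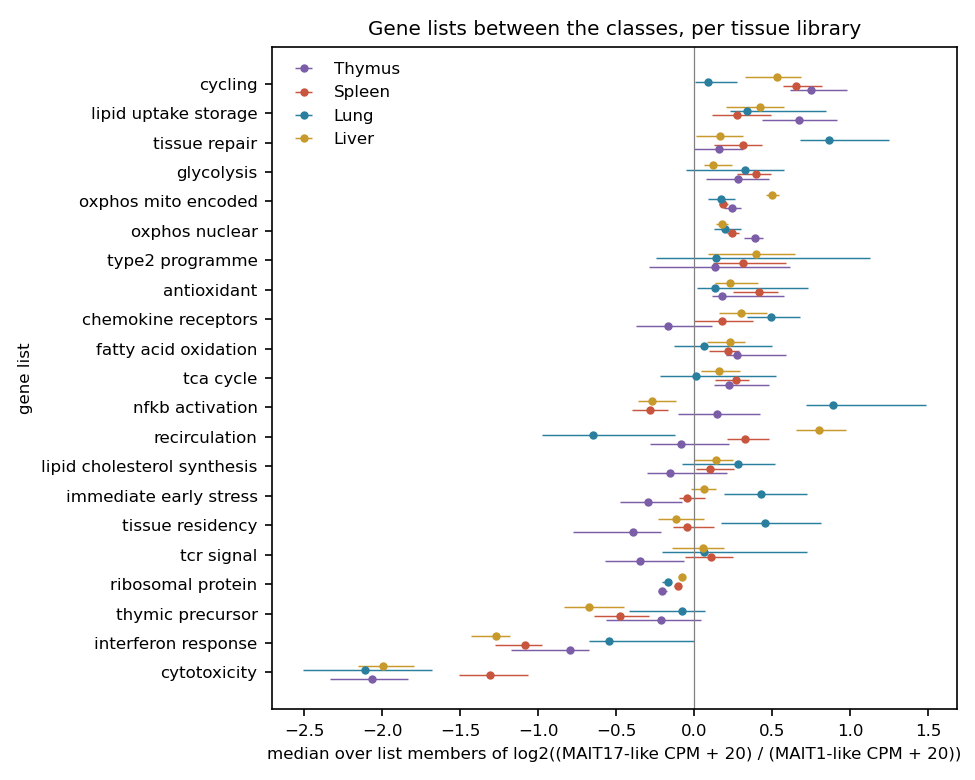
Median log2 difference of MAIT17-like minus MAIT1-like cells for 21 gene lists in each tissue, with intervals for counting error.

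What set MAIT17-like cells of 1 organ apart was the third question, and it was largely a matter of the lung. Crem, a cAMP-responsive transcription factor, stood at 884 CPM in lung (846 to 924) and 21.3, 13.7 and 22.3 CPM in thymus, spleen and liver. Vps37b, an endosomal sorting protein, stood at 1444 CPM in lung against 43.7 to 52.4 CPM elsewhere, and Fosl2, an AP-1 subunit, at 575 (544 to 607) against 14.2 to 50.8 CPM. The histone demethylases Kdm6b, at 545 CPM (515 to 576), and Kdm2b, at 440 (413 to 469), stood at 35.5 to 60.9 CPM elsewhere. Ramp3 stood at 1037 CPM in lung against 80.4 to 135, Rrad at 276 (255 to 298) against 18.9 to 26.2 and Cwc25 at 342 (318 to 367) against 30.2 to 39.3. The lung alone was digested with enzymes, and 75.2% of its MAIT17-like cells were from cluster 3. On GRCm38, Crem lies at chromosome 18 from 3266048 to 3337748 and Vps37b at chromosome 5 from 124004641 to 124032270.

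Lists with the same pattern were the NF-kB targets and the immediate early genes. In lung MAIT17-like cells all 15 NF-kB members stood above the mean of the other tissues, with a median log2 ratio of 1.54 (1.46 to 1.67), above all 10000 matched random lists. The inhibitor gene Nfkbia stood at 1258 CPM against 103 to 283 elsewhere and Tnfaip3 at 397 (372 to 424) against 23.6 to 105. Of 23 immediate early and stress members 20 stood above, with a median of 1.48 (1.39 to 1.57). Junb stood at 3171 CPM against 384 to 1940 and Nr4a1 at 313 (290 to 337) against 2.36 to 45.4. The heat shock gene Hspa1a stood at 248 (228 to 270) against 2.36 to 33.9. In the finest clustering Hspa1a stood at 1709 CPM in the cluster led by heat shock genes but at 17.9 CPM in the one led by Crem. T cell receptor signalling genes had a median of 0.46 (0.33 to 0.66) with 9 of 13 above, which included Nr4a1. Between cells of cluster 0 alone the lung NF-kB median was 0.63, and over all cells of the tissue the receptor signalling median was 0.080.

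Other lists stood apart less in the lung than the NF-kB and immediate early lists. Tissue residency had a median of 0.34 (0.26 to 0.46), with Rgs2 at 611 CPM against 61.8 to 94.0, and tissue repair one of 0.31 (0.22 to 0.46), with Areg at 34.2 CPM (27.0 to 42.7) against 0 to 0.916. Proliferation genes had -0.70 (-0.79 to -0.56) with 0 of 17 above, and Birc5 stood at 3.99 CPM (1.83 to 7.58) against 28.9 to 56.7. The proliferation median was -0.19 with rebuilt clusters, -0.21 with cluster 0 alone and -0.38 over all cells of the tissue, but -1.31 with a pseudocount of 5 CPM. Beside it, 3 markers of double-positive thymocytes had a median of -0.60 (-0.84 to -0.38) with 0 of 3 above, and -0.059 over all cells of the tissue. Glycolysis stood at -0.40 (-0.46 to -0.29), although Hk2 was at 601 CPM against 27.2 to 113, the TCA cycle at -0.37 (-0.41 to -0.24) and the nuclear-encoded respiratory chain at -0.23 (-0.25 to -0.19). The mitochondrially encoded chain went the other way, at 0.20 (0.12 to 0.22) with 13 of 13 above. In lung MAIT1-like cells that chain stood at 0.34 (0.21 to 0.41), and in lung naive T-like cells at 0.23 with 12 of 13 above. It is closely tied to the share of mitochondrial UMIs per cell, whose median was highest in the lung library, at 3.67%. Single genes lowest in lung were the ligand gene Clec2i, at 17.7 CPM (12.7 to 24.2) against 74.2 to 123, the phosphatase gene Ptpn7, at 55.4 (46.2 to 66.1) against 167 to 199, and the receptor gene Cd160, at 10.6 (6.82 to 15.8) against 42.4 to 63.8, a log2 gap of -1.03 that was -1.60 with a pseudocount of 5 CPM. Il16 stood at 27.5 CPM (21.1 to 35.3) against 84.5 to 130 and Ifi27l2a at 46.1 (37.7 to 55.9) against 131 to 191.

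Thymus MAIT17-like cells had low immediate early genes, with a median of -1.27 (-1.38 to -1.13) and 1 of 23 members above the other tissues, below all matched random lists. Fosb stood at 8.27 CPM (3.33 to 17.05) against 223 to 371, Fos at 173 (146 to 203) against 636 to 1215 and Dusp1, a MAP kinase phosphatase, at 87.5 (68.7 to 110) against 390 to 894. The NF-kB median was -0.63 (-0.83 to -0.46), that of receptor signalling -0.47 (-0.64 to -0.31) and that of recirculation -0.34 (-0.51 to -0.26). Each of these list medians was taken against a mean that includes the lung. The activation marker Cd69 stood at 35.5 CPM (23.9 to 50.6) against 137 to 221. The NF-kB median was -0.26 with cluster 0 alone, and that of receptor signalling -0.18 over all cells of the tissue but -0.77 with thinned cells and -0.95 with a pseudocount of 5 CPM. The Ly49 receptor gene Klra1 stood at 86.3 CPM (67.6 to 108) in thymus against 0.444 to 3.21, Ly6a at 196 (167 to 228) against 43.0 to 62.4 and Rtp4 at 82.7 (64.5 to 105) against 9.31 to 21.5. With rebuilt clusters the Klra1 difference ended, as its log2 gap to the nearest other tissue went from 2.20 to -0.059. Interferon response genes had a median of 0.39 (0.30 to 0.64) with 13 of 13 above, and Stat1 stood at 147 CPM (122 to 175) against 53.2 to 116. Hmgn2, a chromatin protein, stood at 435 CPM (392 to 482) against 135 to 236, beside a proliferation median of 0.31 (0.21 to 0.43).

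Spleen and liver MAIT17-like cells stood apart less. In the spleen the early genes Cd69, at 221 CPM (208 to 236), Egr1, at 92.3 (83.5 to 102) against 27.2 to 55.5, and Klf10, at 87.5 (78.9 to 96.7) against 41.3 to 48.5, were highest. The immediate early list nevertheless had a median of -0.27 (-0.36 to -0.21) with 7 of 23 above, against a mean that includes the lung. Dtx1, a Notch pathway gene, stood at 209 CPM (196 to 223) against 24.8 to 153, and Nsun6 at 42.8 (36.9 to 49.4) against 14.2 to 23.9. Fgl2 was lowest there, at 18.3 CPM (14.5 to 22.8) against 51.6 to 86.9, and Rgs1 stood at 77.4 (69.4 to 86.1) against 122 to 183, a log2 gap of -0.54 that was -0.91 with rebuilt clusters. B cell markers had a median of 0.50 (0.41 to 0.60) with 6 of 6 above, beside an NF-kB median of -0.49 (-0.56 to -0.36), which was -0.22 with cluster 0 alone and, as in thymus and liver, was taken against a mean that includes the lung. The B cell median was 0.84 with a pseudocount of 5 CPM. In spleen naive T-like cells it stood at 0.68 with 5 of 5 above, so the rise was not particular to MAIT17-like cells. In the liver the interferon regulatory gene Irf1 stood at 72.4 CPM (58.5 to 88.6) against 28.4 to 41.7 and Rasgrp1 at 167 (146 to 191) against 95.4 to 115. Liver recirculation genes had a median of 0.38 (0.23 to 0.42), with Klf2 at 784 CPM (737 to 834) against 334 to 641, and mitochondrially encoded genes one of -0.22 (-0.26 to -0.18). Mitochondrially encoded genes were low in liver MAIT1-like and naive T-like cells too. The liver NF-kB median of -0.43 (-0.50 to -0.27) was -0.089 with cluster 0 alone, and the Irf1 gap of 0.58 was 0.94 with rebuilt clusters. Genes lowest in liver differed little, such as Magoh at 99.4 CPM (83.0 to 118) against 139 to 178.

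MAIT1-like cells of the thymus expressed the receptor kinase gene Styk1 at 193 CPM (148 to 248) against 0 to 1.08 elsewhere, and the integrin gene Itgae, whose product CD103 binds E-cadherin, at 149 (110 to 198) against 0 to 7.58. Capg, an actin-capping protein, stood at 436 CPM (367 to 514) against 25.1 to 90.9, and the Ly49 genes Klra3, at 206 (159 to 261) against 37.6 to 76.5, and Klra5, at 121 (86.4 to 166) against 6.49 to 25.1. The log2 gap of Klra5 to the nearest other tissue went from 1.65 to 0.52 with rebuilt clusters, and that of Styk1 from 3.34 to 5.03 with a pseudocount of 5 CPM. The lung interval of Klra5 (3.04 to 90.6) overlaps that of the thymus. Lowest there were the kinase gene Txk, at 224 CPM (175 to 282) against 516 to 664, and the AP-1 gene Junb, at 676 (589 to 772) against 1213 to 1913. Immediate early genes had a median of -0.88 (-0.98 to -0.61), with Dusp1 at 237 CPM (186 to 296) against 410 to 765, and the median was -0.48 with thinned cells. NF-kB genes had one of -0.50 (-0.78 to -0.32), and interferon response genes one of 0.44 (0.29 to 0.74) with 13 of 14 above. The finest interferon-high cluster held 12 of the 108 thymus MAIT1-like cells, against 31 of 443 in spleen, 37 of 541 in liver and 1 of 46 in lung. Beside these lists, markers of NK cells and innate lymphoid cells had a median of -0.50 (-0.73 to -0.25). It was -0.24 with rebuilt clusters, -0.27 with cluster 8 and -0.095 over all thymus cells. On GRCm38, Styk1 lies at chromosome 6 from 131299142 to 131353597.

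MAIT1-like cells of the liver expressed Socs2, a cytokine signalling inhibitor, at 94.4 CPM (79.5 to 111) against 12.5 to 24.9, Ccr5 at 67.2 (54.7 to 81.6) against 9.34 to 30.3 and Icam1 at 118 (102 to 137) against 37.4 to 66.0. The chemokine gene Cxcl10 stood at 28.6 CPM (20.7 to 38.5) against 0 to 9.74. The lung intervals of Ccr5 (3.04 to 90.6), Icam1 (13.7 to 128) and Cxcl10 (0 to 46.2) overlap those of the liver, so a higher liver value is not shown against the lung. Ikzf2, which encodes the factor Helios, was lowest in liver, at 130 CPM (112 to 149) against 258 to 489, and Cd7 stood at 208 (186 to 233) against 340 to 891. With rebuilt clusters the log2 gap to the nearest other tissue went from 0.79 to 0.13 for Ccr5, from 0.71 to 0.31 for Cxcl10 and from -0.90 to -0.57 for Ikzf2. Mitochondrially encoded genes had a median of -0.50 (-0.54 to -0.45) with 0 of 13 above, and mt-Cytb stood at 1597 CPM against 2319 to 2656, a log2 gap of -0.53 that was -0.22 with rebuilt clusters. Liver naive T-like cells stood at -0.34 with 1 of 13 above, and the liver library had the lowest median mitochondrial share per cell, at 2.52%. Recirculation genes had one of -0.43 (-0.64 to -0.24), which was 0.15 over all liver cells and -0.71 with rebuilt clusters. Markers of NK cells and innate lymphoid cells stood beside these lists at -0.80 (-0.95 to -0.57) with 1 of 8 above, at 0.080 over all liver cells and at -1.34 with a pseudocount of 5 CPM.

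In the spleen, MAIT1-like cells had low cytotoxicity genes, with a median of -0.44 (-0.59 to -0.29) and 1 of 10 members above, beside a median of -0.47 (-0.73 to -0.20) for markers of NK cells and innate lymphoid cells. The latter was -0.050 with rebuilt clusters, -0.0067 with cluster 8 and -0.054 over all spleen cells. Gzmb stood at 19.5 CPM (11.5 to 30.8) in spleen against 377 (313 to 450) in thymus, 331 (302 to 361) in liver and 188 (105 to 310) in lung. Jund stood at 781 CPM (725 to 841) against 389 to 484, Klf4 at 39.0 (27.3 to 53.9) against 3.11 to 13.96 and Dpp4 at 50.9 (37.4 to 67.6) against 21.8 to 25.1, and the Klf4 gap of 0.80 was 1.21 with a pseudocount of 5 CPM. Nsun6, at 49.8 CPM (36.4 to 66.4) against 12.5 to 25.3, also stood high in spleen MAIT17-like cells. The lung intervals of Klf4 (0.317 to 69.9), Nsun6 (0.317 to 69.9) and Dpp4 (3.04 to 90.6) and the thymus intervals of Nsun6 (10.8 to 49.1) and Dpp4 (8.76 to 44.9) overlap those of the spleen, as the thymus interval of Ifngr1 does (296 to 430). Ctla2a stood lowest, at 183 CPM (156 to 213) against 269 to 464, and Ifngr1, the interferon-gamma receptor, at 271 (238 to 306) against 358 to 802. B cell markers had a median of 0.57 (0.42 to 0.76), with Cd74 at 53.0 CPM (39.2 to 70.1) against 0 to 25.1. The lung interval of Cd74 (3.04 to 90.6) overlaps that of the spleen. The B cell median was 1.44 with a pseudocount of 5 CPM. The rise was shared by spleen MAIT17-like cells, at 0.50, and spleen naive T-like cells, at 0.68.

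The lung held 46 MAIT1-like cells, so its intervals are wide. Vps37b stood at 840 CPM (651 to 1067) against 92.0 to 130 and was highest in lung in both classes, and the apoptosis gene Bcl2l11 stood at 414 (285 to 581) against 28.0 to 65.2. Ptpn22, a phosphatase of receptor signalling, stood at 978 CPM (773 to 1220) against 296 to 328 and Itk at 389 (264 to 552) against 106 to 146. Ly6a was lowest, at 62.7 CPM (20.4 to 146) against 240 to 315, and Neat1 stood at 12.5 (0.317 to 69.9) against 93.4 to 115, where the thymus interval (63.0 to 133) overlaps. With rebuilt clusters the log2 gap of Neat1 to the nearest other tissue turned from -1.80 to 0.52, and gaps went from -1.65 to -0.77 for Ly6a and from 1.30 to 0.72 for Itk. Immediate early genes had a median of 0.49 (0.28 to 0.96), recirculation genes 0.61 (0.37 to 1.09) and interferon response genes -1.08 (-1.32 to -0.77). Over all lung cells these were 1.47, 0.14 and -0.58, and recirculation was 0.99 with rebuilt clusters. Of the 46 cells, 1 was in the finest interferon-high cluster. Sell stood at 263 CPM (163 to 402) against 12.5 to 62.8, and Cxcr6 at 351 (233 to 507) against 1037 to 1203. Markers of NK cells and innate lymphoid cells had a median of 1.89 (1.28 to 2.16) beside these lists, with Ncr1 at 62.7 CPM (20.4 to 146) against 0 to 16.2 and Klra8 at 100 (43.3 to 198) against 3.25 to 21.8. The spleen interval of Ncr1 (9.09 to 26.8) and the thymus interval of Klra8 (8.76 to 44.9) overlap those of the lung. The list median was 1.12 with rebuilt clusters, 1.02 with cluster 8 and 0.0070 over all lung cells. Tyrobp stood at 201 CPM (115 to 326) against 21.8 to 36.8 and Eomes at 75.2 (27.6 to 164) against 0 to 5.41. Klrb1c, at 251 CPM against 258 to 388, was not raised. Cd3e stood at 301 CPM (193 to 448) against 516 to 556, while the Cd3d interval (907 to 1387) covers the other tissues. Whether NK cells were among the 46 cells was not tested, so these lung values may not be those of MAIT1-like cells alone.

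**Figure D4:**
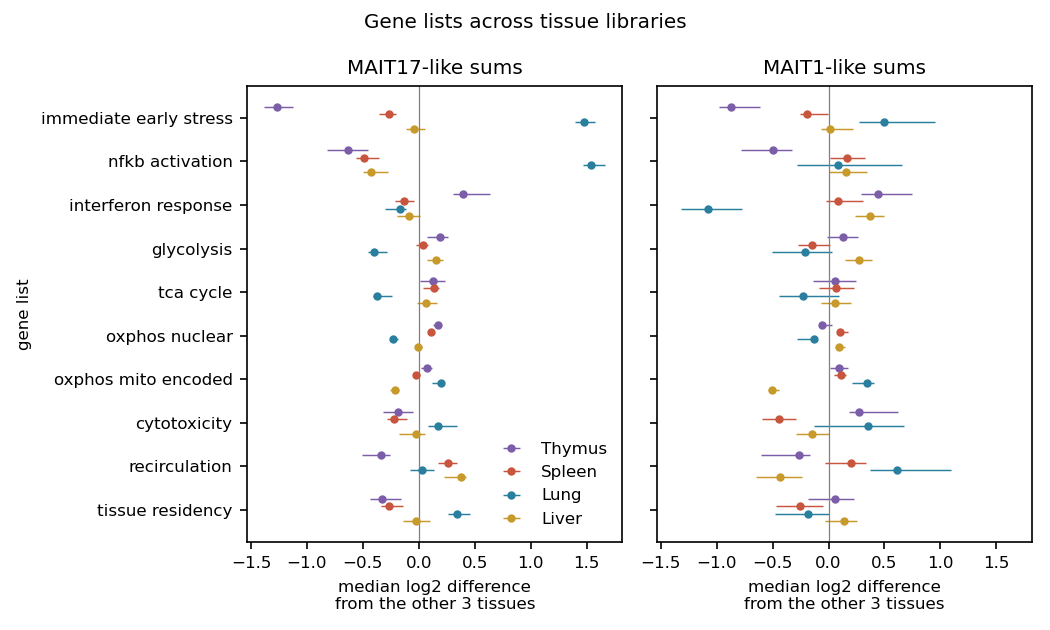
Median log2 ratio of each tissue to the mean of the other tissues for 10 gene lists in MAIT17-like and MAIT1-like cells, with intervals for counting error.

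In which cells effector transcripts were detected without stimulation was the last question, asked with each cell thinned to 1000 UMIs. Only the lung was digested with enzymes, and its MAIT17-like cells held high immediate early and NF-kB genes. A higher share in the lung therefore cannot be told apart from an effect of digestion. A cell without a UMI at this depth is not shown to lack the transcript, and the share that background RNA gives was not measured. Il17a and Ifng were among the markers that named the classes, so their differences between the classes are a check of the names. Il17a was found in 7.31% of lung (5.76 to 9.12), 4.75% of liver (2.84 to 7.40), 1.91% of spleen (1.26 to 2.76) and 0.535% of thymus MAIT17-like cells (0.0135 to 2.94). It was found in 1 of 1123 MAIT1-like cells, or 0.0890%. Unthinned, the MAIT17-like shares were 11.4%, 9.84%, 4.08% and 1.07% at median depths of 2108, 3116, 2872 and 4502 UMIs, against 0.351% of MAIT1-like cells at 2340.5 UMIs. Il22 was found in 1.93%, 1.32%, 0.565% and 0.535% of lung, liver, spleen and thymus MAIT17-like cells, unthinned 2.99%, 4.92%, 1.38% and 1.07%, and in 0 of 1123 MAIT1-like cells, which allows a share of cells with a UMI of up to 0.267%. Il17f was found in 1.12%, 1.06% and 0.565% of lung, liver and spleen MAIT17-like cells, unthinned 2.70%, 1.81% and 1.24%, and in 0 of 1123 MAIT1-like cells, a limit of 0.267% again. Areg was found in 2.44% of lung MAIT17-like cells (1.57 to 3.60), unthinned 4.15%, against 0.141% in spleen, and in 1 of 42 lung MAIT1-like cells, or 2.38% (0.0603 to 12.6). Shares of MAIT1-like cells over all tissues rest on few lung cells, 42 of 1123, against 985 of 2968 MAIT17-like cells.

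Ifng was found in 11.9% of liver (9.28 to 14.9), 5.98% of spleen (3.94 to 8.64), 0.926% of thymus (0.0234 to 5.05) and 2.38% of lung MAIT1-like cells (0.0603 to 12.6), and in 0.270% of MAIT17-like cells. Unthinned, these were 25.9%, 12.6%, 5.56% and 4.35% at median depths of 2662, 1984, 2764.5 and 1634 UMIs, against 0.687% of MAIT17-like cells at 2614 UMIs. Il4 was found in 7.81% of liver (5.68 to 10.4), 4.60% of spleen (2.83 to 7.01) and 3.70% of thymus MAIT1-like cells (1.02 to 9.21), unthinned 14.8%, 9.03% and 11.1%, and in 0.202% of MAIT17-like cells. Gzmb was found in 25.9% of thymus (18.0 to 35.2), 21.2% of liver (17.8 to 24.9), 7.14% of lung (1.5 to 19.5) and 1.15% of spleen MAIT1-like cells (0.374 to 2.66), unthinned 44.4%, 34.0%, 15.2% and 3.16%. Among MAIT17-like cells it was found in 3.74%, 2.64%, 7.11% and 1.69% of thymus, liver, lung and spleen cells. Gzma was found in 8.33%, 3.53%, 9.52% and 1.38% of thymus, liver, lung and spleen MAIT1-like cells, unthinned 10.2%, 4.81%, 17.4% and 2.93%, against 0.438% of MAIT17-like cells. Tnf was found in 4.95% of MAIT17-like and 3.12% of MAIT1-like cells over all tissues, and Csf2 in 1.25% of each, unthinned 11.6% and 7.21% for Tnf and 2.98% and 3.34% for Csf2.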

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

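The divided UMIs and the left-out tissues were alternatives fixed before the data were seen, but their bounds as tests here, and the tests of splits, the date-like code, free RNA and digestion, were chosen after the result was seen, and leaving out the interferon-high cells was added after seeing the data, before its own result. Of 45 groups of 4 tissues examined, 7 held a tissue standing far from the other 3. Chance gives about 1 in 20 groups for independent normal values. CPM of genes chosen from these same sums need not follow that rate, so no excess over chance is claimed. In MAIT17-like cells the lung stood apart for Ramp3, at 1037 CPM against 80.4 to 135 in the other tissues, for Hk2, at 601 CPM against 27.2 to 113, and for Avpi1, at 323 CPM against 58.2 to 68.6. These genes were among the leading genes of cluster 3, whose cells were all from the lung, so their high lung values are not separate evidence. In MAIT1-like cells the thymus stood apart for Pglyrp1, at 193 CPM against 113 to 122, and the lung for Serpinb9, at 364 CPM against 37.9 to 46.7. The class difference of T cell receptor signalling genes was -0.34 in the thymus against 0.06 to 0.11 elsewhere, and that of cytotoxicity genes -1.31 in the spleen against -2.11 to -1.99. For receptor signalling the thymus interval (-0.57 to -0.06) overlaps those of the lung (-0.21 to 0.72) and liver (-0.14 to 0.19). The lung value of Pglyrp1 rests on 46 cells, so its distance from the thymus is loosely known. The authors' finest clustering, which the main comparisons did not use, and the unnamed group, which the class test left out, gave 3 more observations. Each was above the limit that a count of 0 allows, a bound that any cluster with more than 3 cells in the tissue passes. A finest cluster led by the heat shock genes Hspa1a, Hspa1b and Dnajb1 made up 8.99% of lung cells, 118 of its 122 cells. Another led by the interferon genes Ifit3, Ifit1 and Isg15 made up 3.61% of liver cells, and the unnamed Gzma, Ccl5 and Gzmk group 3.12% of lung cells.

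Genes that differed between MAIT17-like and MAIT1-like cells numbered 1695. Of the 8 splits of the sums that part all 4 pairs from the same tissue, 1 gave as many, the real one, and the highest other gave 82, but 8 splits are too few for a share under 0.05. The other splits put both sums of some tissues in the same group, and the highest of them gave 181. Use of the same UMIs for clustering and testing is argued against as the whole account, since 903 of the genes were called in the same direction when the classes came from 1 portion of the UMIs and the test from the rest. What the class p-values mean beyond these clusters stays open, because the classes were built by clustering these cells.

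Interferon response genes were higher in MAIT1-like cells, with 13 of 14 called. A small set of interferon-high cells, 81 of them MAIT1-like, accounted for part of the size and not the whole, as 11 members stayed called without them and the list median went from -2.13 to -1.30. A single library was not behind the calls, since at least 12 members stayed called whichever tissue was left out. A biological difference between the classes may remain, as a hypothesis from these data only, and the call on the list as a whole was lost with an estimated correlation, at 0.408.

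Genes at least 2-fold higher in lung MAIT17-like cells than in spleen and liver numbered 151, a set chosen from these libraries, with a lung median of 1.61. The date-like code that the lung shares with the thymus is argued against, since the thymus median of these genes was -0.11 (quartiles -0.43 to 0.13). Free RNA from MAIT17-like cells is also argued against, though by unlike measures. Lung naive T-like cells carried 27.0% of the excess of these genes over the other tissues (quartiles 8.80 to 43.9). For 13 MAIT17-like markers they held 2.54% of the lung MAIT17-like level, with no other tissue subtracted. Enzymatic digestion of the lung and a biological difference of the organ cannot be told apart, as no undigested lung library is here. The median was 0.77 in lung naive T-like cells, with 138 of 151 genes above the other tissues, and 0.77 in MAIT1-like cells, with 123. Other classes may therefore have shared part of the change. The NF-kB list, at 1.54 in lung MAIT17-like cells, stood at 0.086 in MAIT1-like cells, where the interval (-0.28 to 0.65) covers both directions. In naive T-like cells it stood at 0.15, at percentile 98.6 of matched random lists, with 10 of 15 members above.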

How the results depend on the processing

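The alternatives with cluster 0 alone, with cluster 8, without the robust option and without interferon-high cells were chosen after seeing the data. For values that changed, the cause was not tested, except that thinning and dividing the UMIs left fewer counts. Of single genes between the classes, 1405 of 1617 values kept direction and side of the threshold, 209 lost the call and 3 turned. Of the 24 leading genes 13 kept the call in all 17 alternatives and 0 turned. Of gene values across tissues 225 of 256 stayed within counting error, 29 moved and 2 turned, and of shares with a UMI 53 of 80 stayed and 27 moved. Depth limits mostly the lung MAIT1-like sum, of 79763 UMIs from 46 cells.

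Counts of genes higher and lower in MAIT17-like cells were 422 and 469 with the DESeq2 Wald test, 467 and 519 with the UMIs divided, and 393 and 467 with thinned cells. Leave-one-out counts ranged from 386 to 837 and from 425 to 852, lowest without the liver, and the count was 501 without the spleen.

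Without the replicate block, 363 genes were higher and 356 lower. The adjusted p was 0.101 for precursor genes, 0.230 for proliferation, 0.0850 for lipid uptake, 0.160 for mitochondrially encoded genes and 0.134 for tissue repair, all lost, and 0.0410 for antioxidant genes, now past. Type 2 (0.559), immediate early (0.907) and NF-kB genes (0.939) turned.

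Leave-one-out adjusted p-values ranged from 0.536 to 0.975 for type 2 (turned without the liver or lung), from 0.0176 to 0.970 for residency (lowest without the lung, turned without the thymus) and from 0.559 to 0.996 for recirculation (turned without the liver, 0.605). They ranged from 0.292 to 0.996 for immediate early genes (turned without the thymus), from 0.0772 to 0.863 for NF-kB (turned without the liver, 0.678, or spleen, 0.628) and from 0.317 to 0.996 for cholesterol synthesis (turned without the spleen). The ranges were 0.00616 to 0.266 for mitochondrially encoded genes (lost without the liver, and without the lung at 0.102), 0.0293 to 0.109 for antioxidant genes (past without the liver, and without the lung at 0.0376), 0.235 to 0.874 for chemokine receptors (turned without the lung, and without the liver at 0.608) and 0.00870 to 0.334 for tissue repair (lost without the lung).

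With an estimated correlation the adjusted p was 0.346 for precursor and for lipid uptake genes, 0.476 for proliferation and for nuclear-encoded respiration, 0.609 for mitochondrially encoded, 0.416 for tissue repair, 0.113 for cytotoxicity, 0.578 for ribosomal and 0.408 for interferon genes. With the UMIs divided, proliferation (0.0553), recirculation (0.505), immediate early genes (0.439) and 2810417H13Rik (0.216) turned and nuclear-encoded respiration (0.106) was lost. With clusters rebuilt without list genes, proliferation (0.0682) was lost, and recirculation, immediate early and NF-kB genes (0.898 each) and chemokine receptors (0.917) turned. With cluster 0 alone, proliferation (0.161), immediate early (0.326), cholesterol synthesis (0.911) and 2810417H13Rik (0.906) turned and lipid uptake (0.0710) was lost. With cluster 8 as MAIT1-like, proliferation (0.245), nuclear-encoded respiration (0.0666) and mitochondrially encoded genes (0.0651) were lost, and recirculation (0.561), immediate early (0.576), NF-kB (0.756) and chemokine receptors (0.112) turned. Without interferon-high cells, tissue repair (0.0687) was lost and immediate early genes (0.981) turned. Of 231 list values 175 kept direction and side, 24 lost the call, 4 gained it and 28 turned.

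With rebuilt clusters 2810417H13Rik between the classes turned (0.858), MAIT17-like cells were 42.8% of spleen and MAIT1-like cells 5.71% of lung, and Klra1 in thymus (-0.059) and Neat1 in lung (0.52) turned. Marker-only classes also took in cells of the other classes. They gave MAIT17-like shares of 49.0% in thymus and 72.4% in lung. Their MAIT1-like shares were 36.6%, 51.3%, 23.5% and 63.0% in thymus, spleen, lung and liver. Of both classes together, MAIT17-like cells were 63.4%, 76.5%, 95.8% and 41.6%, and MAIT1-like cells 36.6% in thymus, 23.5% in spleen and 58.4% in liver.

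For lists across tissues, 96 of 147 values stayed, 49 moved and 2 turned. Rebuilt clusters gave -0.19 for lung proliferation, -0.71 for liver recirculation, -0.39 for liver mitochondrial genes, -0.60 for spleen cytotoxicity and -0.76 for lung interferon genes. Thinning gave -0.49 for lung proliferation, -0.77 for thymus receptor signalling and -0.48 for immediate early genes of thymus MAIT1-like cells. A pseudocount of 5 CPM gave -1.31 for lung proliferation, -1.57 and -1.09 for thymus immediate early genes of MAIT17-like and MAIT1-like cells, -0.59 and 1.82 for NF-kB in spleen and lung, -0.95 and 1.09 for receptor signalling in thymus and lung, and -1.44 for lung interferon genes. Members of at least 20 CPM gave -0.90 for lung proliferation, -0.77 for thymus receptor signalling and 0.96 for immediate early genes of lung MAIT1-like cells. All cells of a tissue gave -0.38 for lung proliferation, -1.09 and 1.47 for immediate early genes of thymus and lung, -0.18 and 0.080 for receptor signalling of thymus and lung, 0.14 and 0.15 for recirculation of lung and liver (the latter turned), -0.38 for liver mitochondrial genes, -0.58 for lung interferon genes and 0.080 for liver NK cell markers (turned). Cluster 0 alone gave -0.21 for lung proliferation, -1.39 for thymus immediate early genes and -0.26, -0.22, 0.63 and -0.089 for NF-kB in thymus, spleen, lung and liver. With cluster 8, liver mitochondrial genes stood at -0.43. Of 40 class shares 25 stayed and 15 moved.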

Other observations

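Naive T-like cells also differed between organs, in 1 library each, and 120 of the 178 lung cells of this class belonged to a finest cluster with 1 cell from another tissue. In the thymus their interferon response genes had a median of 0.85 with 13 of 14 above the other tissues, and Stat1, a carrier of interferon signals, stood at 318 CPM (261 to 384) against 101.2 to 127. Proliferation genes had a median of 0.95 there, with 15 of 15 above. Their glycolysis genes had a median of 0.60 in thymus and -0.72 in lung, with Ldha, which makes lactate, at 731 CPM (643 to 828) in thymus and 269 (217 to 330) in lung. Recirculation genes had a median of -0.74 in thymus and 0.41 in lung, and Klf2 stood at 410 CPM (344 to 484) in thymus against 997 to 1261. Immediate early genes stood at -0.74 in thymus and 0.86 in lung. NF-kB genes stood at 0.15 in lung, at percentile 98.6 of matched random lists, with Tnfaip3 at 188 CPM (145 to 240) against 17.7 to 73.9.

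In the authors' finest clustering, 120 of 121 cells of a cluster led by Ccr7, at 702 CPM, were from the lung, and all 121 were in the naive T-like class. The lung cluster led by heat shock genes held Hspa1a at 1709 CPM and Dnajb1 at 1548 CPM, and also Nr4a1 at 406 CPM and Il22 at 99.6 CPM. A cluster of 84 cells led by Ccnb2, at 584 CPM, and Cdc20, at 325 CPM, came from all 4 tissues, with 18 thymus, 42 spleen, 6 lung and 18 liver cells. The 46 lung MAIT1-like cells held the T cell gene Cd3e at 301 CPM (193 to 448) against 516 to 556 in other tissues, Cd3g at 928 (728 to 1165) against 1277 to 1803 and Cd3d at 1128 (907 to 1387) against 1168 to 1246, beside Eomes, a factor of NK and memory T cells, at 75.2 (27.6 to 164) against 0 to 5.41.

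The test of 1 hypothesis about the naive T-like cells was chosen after the result was seen. Conventional naive T cells in the sort gate may make up part of the naive T-like class. Zbtb16, which MAIT cells express, stood at 7.97 CPM in its Cd8b1-expressing cluster, near the 7.51 CPM of precursor-like cells. In its Cd4-expressing cluster Zbtb16 stood at 53.6 CPM, near the 55.2 CPM of the MAIT1-like cluster, against 93.4 to 129 CPM in the MAIT17-like clusters. This hypothesis stays open, as the table held no T cell receptor transcripts. Precursor-like cells were low too, so a low value does not tell conventional from immature cells.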
